A study of Mus musculus with 48 samples.

How the data were processed

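RNA of whole kidney from 48 female BALB/c mice in 8 groups of 6 was hybridised as biotin-labelled cRNA to single-colour Affymetrix arrays, 1 mouse per array, per the labels. Every mouse has its own number in the labels, no number is shared between groups and no batch is named, so mice were treated as independent and unpaired. Sets of arrays with shared residuals, found later from the values, largely followed mouse order within the groups. The arrays may therefore not be fully independent. The deposited table holds 45101 probe sets as intensity values on a linear scale, made with GCRMA per the submitters' processing notes. The version of GCRMA and which arrays were normalized together are not given in the sources used here. Values ran from 1.78 to 63594 with none missing and none under 1, and log2 was taken without an offset. No pair of arrays held identical values.

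Array medians (log2 intensity, in order of mouse number) were 3.47, 3.36, 3.36, 3.35, 3.37 and 3.34 in iv saline, 3.35, 3.5, 3.36, 3.37, 3.4 and 3.36 at iv 50, 3.37, 3.36, 3.55, 3.38, 3.37 and 3.37 at iv 200, and 3.43, 3.52, 3.39, 3.42, 3.41 and 3.42 at iv 400 mg/kg. They were 3.54, 3.55, 3.58, 3.49, 3.51 and 3.55 in ip saline, 3.51, 3.49, 3.53, 3.49, 3.55 and 3.5 at ip 50, 3.52, 3.47, 3.5, 3.52, 3.56 and 3.51 at ip 200, and 3.64, 3.68, 3.6, 3.63, 3.59 and 3.65 at ip 400 mg/kg. The 90th percentile lay between 8.28 and 8.75 in iv arrays and between 9.07 and 9.23 in ip arrays. The number of arrays limits the precision.

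The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, and probe sets with several were not named. In the table used here the values do not follow the probe set identifiers beside them. Across 30406 pairs of probe sets listed for the same gene the levels correlated at 0.041 and the within-group residual profiles, after removal of 4 principal components, at a mean of 0.032. The order of values was therefore compared with the order of identifiers, in windows of 1000 probe sets moved by 250, using the same-gene pairs of 70% of the genes. A stretch was accepted where at least 5 windows in a run shared an offset. The accepted stretches were positions 751 to 3250 (offset 64), 5001 to 11750 (offset -47) and 34251 to 36000 (offset -16168).

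In the held-out genes the correlation of levels in these stretches was 0.536, 0.522 and 0.635 over 162, 444 and 47 pairs. The highest value at other offsets within 1000 positions of the accepted one was 0.511, 0.414 and 0.538, so the margins are small. Offsets further away were not compared in this way. At the neighbouring offsets it was 0.095 and 0.221, 0.171 and 0.222, and -0.045 and -0.05. Over held-out pairs with both levels above 6 the residual profiles correlated at 0.374 (285 pairs), against 0.053 (221 pairs) in the same stretches as listed. Of 10 tables with shuffled values 0 gave a stretch, and in a simulated table of 12000 probe sets with blocks moved all 9000 named probe sets were right. Shuffling also removed any likeness between neighbouring values, and the simulated blocks were clean, whereas most positions of the real table followed no accepted offset. Neither check therefore shows how often a false run arises in a table such as this one.

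This reconstruction was chosen after the values were seen, several forms of the scan were tried, and earlier scans used all genes, so the held-out genes are not fully independent. The score per window did not discriminate (161 of 177 windows passed it); the run at a constant offset did. Names were given to 10198 of the 11000 probe sets in the stretches, 7859 genes, and 34101 probe sets stayed outside them. A name rests on the position of a value in the table and not on a stated pairing, and every named result holds only as far as the reconstruction does. Counts over all probe sets, which need no name, are given among the alternatives.

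A probe set was kept where its log2 value was above the table's median (3.47) in at least 6 arrays, which left 24930, and the kept probe set with the highest mean stood for each of 5748 genes. Group means under 3.47 are not told from background, so the size of any change from or to such a level is approximate. All 8 groups were fitted together with limma (lmFit, contrasts.fit, eBayes with trend, residual degrees of freedom 40). The moderated test was two-sided, with Benjamini-Hochberg adjustment over the genes of each of the 10 comparisons and a threshold of 0.05. The interaction is the 400 mg/kg effect by ip minus that by iv. Whole lists were tested with camera at a preset correlation between genes of 0.01, and also with an estimated correlation and with fry. Of 32 lists 26 had at least 5 tested members. The neutrophil, T and NK lymphocyte, B and plasma cell, red blood cell, adrenal, and muscle, pancreas, spleen and liver lists had fewer and were not tested, so cells of these kinds are not excluded.

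On simulated data with 200 of 5748 genes changed, the test recovered 32% at a log2 change of 0.5 and 90.5% at 1 for iv 400 mg/kg against saline, 42.5% and 91.5% for ip 50 mg/kg, and 11% and 72.5% for the interaction. Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls with adjusted p under 0.05 at 400 mg/kg against saline whose 6 treated values lay on 1 side of the saline mean, and the 5 largest for other comparisons. It added the 3 members with the smallest adjusted p of each called list, and 21 fixed genes, of which 12 were tested. Symbols without a name of function were passed over, 1 rise each at iv 50, 200 and 400 mg/kg. Members that moved against their list, and members of lists that were not called, were named after their values were seen. Lcn2, Spp1, Timp1, Fgb, C3, C4b, Hmox1, Top2a and Kap were not analysed here.

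Alternatives were no filter, a filter at the 75th percentile, all probe sets, the mean of a gene's probe sets, quantile normalization, median centring, array weights, only the groups compared, eBayes without trend or with robust fitting, a threshold of 0.01, and leaving out each array. Chosen after the data were seen were leaving out 3 arrays with a low 90th percentile, sets of arrays with shared residuals as a block, names as listed, and interactions at 50 and 200 mg/kg. The planned comparison of 3' and 5' control probe sets as a sign of RNA quality was not run, since the control probe sets lie outside the named stretches. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.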

Results

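Gene expression was measured in whole kidney of 48 female BALB/c mice given 7 daily doses of vancomycin or saline and killed on day 8. Vancomycin is a glycopeptide antibiotic whose dose-limiting toxicity falls on the kidney. The drug was injected intravenously (iv) or intraperitoneally (ip) at 50, 200 or 400 mg/kg per day, and each route had its own saline group, which gave 8 groups of 6 mice. Each mouse was hybridised to its own single-colour Affymetrix array. Array medians ranged from 3.34 to 3.55 (log2 intensity) over the 24 iv arrays and from 3.47 to 3.68 over the 24 ip arrays, and the number of arrays sets the precision of every value.

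Gene names in the results rest on a reconstruction. Under the identifiers as the table used here lists them, probe sets of the same gene did not resemble each other (correlation of levels across 30406 pairs, 0.041). Names were therefore given only to 3 stretches of the table whose values followed the identifier order at a constant offset, 24.4% of all probe sets. In genes held out from the search the correlation in those stretches was 0.471 over 875 pairs, against 0.141 over 947 pairs of held-out genes in the same stretches as listed. All names below carry this limit, and genes outside those stretches were not analysed here by name. Of the genes so named, 5748 passed the filter on low values and were tested in each comparison with limma.

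The effect of the highest iv dose was measured first, against iv saline. Kidneys of iv 400 mg/kg mice had much higher levels of tubular injury genes and much lower levels of genes of the differentiated tubule. Serpina10, which encodes a protease inhibitor of coagulation, rose by 7.80 ± 0.61 (log2 fold change, SE, adjusted p = 3.6e-14) to 11.04 ± 0.37 (SD, n = 6), and Krt20, an epithelial keratin, rose by 6.19 ± 0.49 (adjusted p = 6e-14) to 9.15 ± 1.18. Their iv saline means, 3.24 and 2.96, lay under the table's median of 3.47, where a level is not told from background, so the sizes of these rises are approximate. The injury marker Havcr1, known as KIM-1, rose from 9.64 ± 0.59 to 13.19 ± 0.52 (log2 intensity, SD, n = 6 per group) and clusterin, Clu, from 10.06 ± 0.52 to 14.21 ± 0.19. Hpd, an enzyme of tyrosine breakdown, fell 99.5-fold, from 13.27 ± 0.23 to 6.63 ± 2.30 (SD, n = 6 per group, adjusted p = 8.1e-13). In each of these 5 genes all 6 treated kidneys lay on the same side of the saline mean.

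Other large rises at iv 400 mg/kg were those of the interleukin 36 gene Il1f6 (log2 fold change 5.74), Lrg1 (5.69), the lipopolysaccharide co-receptor Cd14 (5.31), collagen Col1a1 (5.26), the cytokine signalling inhibitor Socs3 (5.21), the adhesion receptor Cd44 (5.18), the chemokine Ccl9 (5.01) and the amine oxidase Aoc1 (5.00). The iv saline means of Il1f6 (2.56), Socs3 (2.43) and Cd44 (2.80) also lay under 3.47, and the sizes of their rises are approximate too. The largest falls after Hpd were in the calcium-binding protein gene Pvalb (-4.17), Dnase1 (-3.86), Clec2h (-3.78), the steroid enzyme gene Hsd3b2 (-3.62), the organic anion transporter family gene Slc22a29 (-3.50), Dpys of pyrimidine breakdown (-3.48), Gatm of creatine synthesis (-3.45), the brush border protease gene Mep1b (-3.37) and Igfbp1 (-3.36). Among the other genes fixed for inspection, the cell cycle inhibitor Cdkn1a rose by 1.79 on the log2 scale. The phosphate transporter Slc34a1 fell by 2.00, the organic anion transporter Slc22a6 by 1.36 and megalin, Lrp2, by 1.95 on the log2 scale. Smaller rises passed the test for complement factor Cfb (0.79, adjusted p = 4.7e-05) and the glutathione synthesis gene Gclc (0.59, adjusted p = 0.038), and uromodulin, Umod, fell by 0.28 (adjusted p = 0.0031). The call on Gclc ended when array weights were used (adjusted p = 0.082) and when only the 2 groups were fitted (adjusted p = 0.087). The water channel Aqp2 (-0.46, adjusted p = 0.21) and the podocyte gene Nphs1 (-0.08, adjusted p = 0.73) did not pass.

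**Figure D1:**
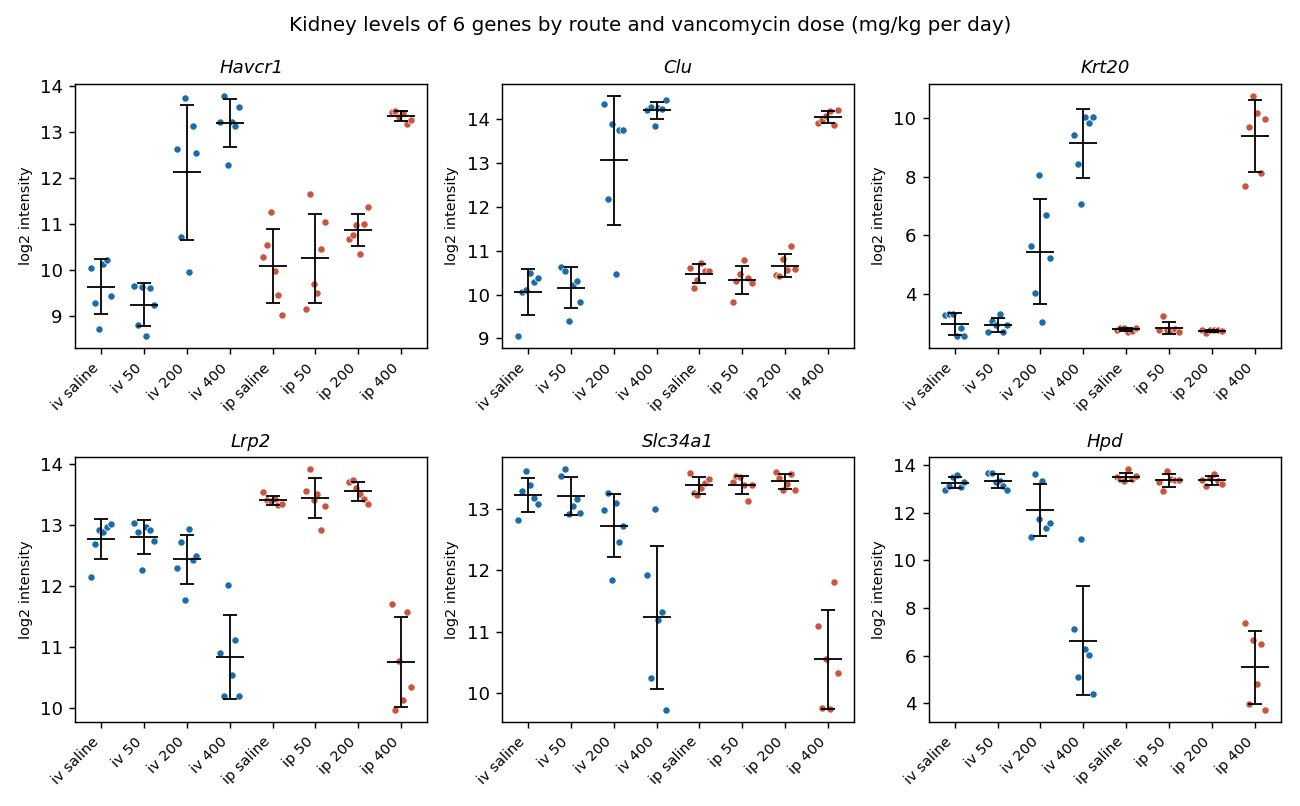
Log2 intensity (y axis) of 6 genes in each kidney by route and dose (x axis, mg/kg per day), with points for mice and bars for the mean and SD of 6 mice. Havcr1, Clu and Krt20 are higher and Lrp2, Slc34a1 and Hpd lower in both 400 mg/kg groups than in saline, and for Havcr1, Clu and Krt20 the iv 200 mg/kg kidneys range from the saline level to near or within the range of the 400 mg/kg kidneys.

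By gene list, injury and immune groups rose at iv 400 mg/kg in camera with a preset correlation. With an estimated correlation the adjusted p of these 8 lists lay between 0.081 and 0.09 and no call was left. Of 21 tested tubular injury genes, 19 rose and none fell (median log2 fold change 3.38), including Cd44, Krt20 and the copper carrier Cp (3.29). Of 22 macrophage and other myeloid genes, 21 rose (median 2.98), among them Ncf4 (4.02), Ly86 (4.58) and C1qa (3.77). The complement list had 10 rises and 1 fall among 12 genes (median 1.63), with Cfi at 3.80 and C1qb at 2.95. Inflammatory signals had 13 rises and 1 fall among 15 (median 1.71), with the adhesion molecule Icam1 at 3.40 and the NF-kB subunit Relb at 2.97. All 10 antigen presentation genes rose (median 2.10), including the immunoproteasome gene Psmb8 (3.16) and H2-DMa (2.87), and 18 of 19 interferon response genes rose (median 1.82), including Irf7 (3.24) and Cxcl10 (3.61). Extracellular matrix genes rose in 21 of 22 cases (median 2.06), with Col1a2 at 4.19 and Sparc at 2.27, and cell cycle genes in 20 of 22 with 1 fall (median 1.79), with Rrm2 at 4.83, Birc5 at 4.53 and Aurka at 3.48. Since 3 complement genes also stand in the myeloid list (C1qa, C1qb and Itgam) and Cxcl10 stands in both the inflammatory and the interferon list, these counts are not independent of each other.

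Lists of tubule segments and mitochondria fell at iv 400 mg/kg in camera with the preset correlation, and these 8 calls were lost with an estimated correlation (adjusted p from 0.081 to 0.4). Among proximal tubule transporters 24 of 27 fell and 1 rose (median -1.25), with Slc7a8 at -2.11 and Slc22a18 at -2.24, while Slco3a1 rose by 1.72. Proximal tubule metabolism had 20 falls and 3 rises among 26 genes (median -1.03), with Hao2 at -1.73 and a rise of the oxysterol hydroxylase Cyp7b1 (2.19). Loop and distal tubule genes fell in 13 of 17 cases (median -1.10), including Egf (-3.14) and Klotho, Kl (-2.34). Collecting duct genes fell in 10 of 13 (median -0.75), including Hmx2 (-2.22) and the sodium channel subunit Scnn1a (-1.03). Oxidative phosphorylation genes fell in 21 of 29 (median -0.37), with the complex II genes Sdha at -1.15 and Sdhb at -0.69. Fatty acid oxidation had 9 falls and 3 rises among 19 genes (median -0.41), with Bdh1 at -2.56 and Acox2 at -1.94. Cholesterol synthesis had 4 falls among 10 genes (median -0.56), with Cyp51 at -2.28, and circadian clock genes fell in 8 of 15 (median -0.45), with Ciart at -2.82 and Hlf at -2.41. The camera test of these 16 lists with a preset correlation gave adjusted p from 1.1e-12 for tubular injury and 5.6e-13 for myeloid genes to 0.011 for cholesterol synthesis. With an estimated correlation adjusted p was 0.081 for tubular injury and myeloid genes, 0.1 for proximal tubule transporters and 0.4 for fatty acid oxidation. Counts adjusted over the list alone were 19 genes for tubular injury, 21 for myeloid genes, 25 for proximal tubule transporters and 21 for oxidative phosphorylation.

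In all, 2859 of 5748 genes passed the limma test at iv 400 mg/kg, 1767 up and 1092 down, and 894 of them changed over 2-fold. The share of rises was 61.8%, and it was 42.5% with each array centred on its median. That setting moved the median log2 fold change of all genes from 0.09 to -0.08, so small changes are read relative to these shifts.

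The same dose by the ip route was compared with ip saline. Serpina10 rose by 7.89 ± 0.61 (log2 fold change, SE, adjusted p = 4.3e-15), Il1f6 by 7.22 ± 0.49 (adjusted p = 1.4e-16) and Cd44 by 6.79 ± 0.33 (adjusted p = 5.8e-21). These sizes are approximate, since the ip saline means of Il1f6 (2.27) and Cd44 (2.95) lay under the table's median of 3.47 and that of Serpina10 (3.74) near it, and the same holds for Krt20 (2.77), Lrg1 (3.29) and Socs3 (2.07). Hpd fell 257-fold, from 13.51 ± 0.18 to 5.50 ± 1.55 (SD, n = 6 per group), and Dnase1 fell 62.3-fold. Havcr1 reached 13.34 ± 0.11 against 10.08 ± 0.80 in ip saline (SD, n = 6 per group, log2 fold change 3.26), and Clu rose by 3.56. All 6 treated kidneys lay on the same side of the saline mean in each of these genes.

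The other large ip 400 mg/kg rises were in Krt20 (6.63), the phosphate transporter Slc34a2 (6.41), Lrg1 (6.25), Col1a1 (6.17), Socs3 (6.03), Ms4a6b (6.02) and Aoc1 (5.90), and the other large falls in Pvalb (-5.83), Clec2h (-5.14), Aspdh (-5.04), the organic anion transporter Slc22a8 (-4.76), Dpys (-4.67), Slc22a22 (-4.66), Mep1b (-4.42) and Slc22a29 (-4.40). Cd14 rose by 5.78 and Cdkn1a by 2.38, and Slc34a1 fell by 2.85, Slc22a6 by 2.91, Lrp2 by 2.66 and Nphs1 by 1.04 on the log2 scale. Cfb (0.57, adjusted p = 0.0019) and Gclc (0.57, adjusted p = 0.038) rose, Umod fell by 0.29 (adjusted p = 0.0017), and Aqp2 did not pass (0.21, adjusted p = 0.56).

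Injury and immune lists rose at ip 400 mg/kg with the preset correlation. All 8 of these calls were lost with an estimated correlation (adjusted p from 0.096 to 0.12). Of 21 tubular injury genes 20 rose (median log2 fold change 3.52), with Ankrd1 at 5.23, and so did all 22 myeloid genes (median 4.27), with Ly86 at 5.90 and the monocyte chemokine receptor Ccr2 at 5.34. All 22 extracellular matrix genes (median 2.59, Col1a2 5.46, Vcan 3.89) and all 10 antigen presentation genes (median 2.28, Psmb8 3.49) rose. Interferon response had 18 rises among 19 (median 2.11, Irf7 4.22), inflammatory signals 14 rises and 1 fall among 15 (median 2.31, Relb 4.29), cell cycle 19 rises and 2 falls among 22 (median 2.52, Mki67 5.64), and complement 9 rises and 1 fall among 12 (median 2.43, C1qb 4.29).

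Proximal tubule transporters fell in 26 of 27 cases at ip 400 mg/kg (median -1.83), with the urate transporter Slc22a12 at -2.73, and proximal tubule metabolism in 22 of 26 with 3 rises (median -1.71), with Ddc at -2.74 and Cyp7b1 at 3.44. Oxidative phosphorylation genes fell in 28 of 29 (median -0.66, Ndufs1 -1.39), loop and distal tubule genes in 16 of 17 (median -1.23, Egf -4.37), fatty acid oxidation genes in 14 of 19 with 2 rises (median -0.81, Acox2 -2.99), collecting duct genes in 9 of 13 (median -0.54, the anion exchanger Slc4a1 -2.42) and cholesterol synthesis genes in 7 of 10 (median -0.74, Cyp51 -2.72). Nrf2 targets had 9 falls and 2 rises among 16 (median -0.45), with the glutathione transferases Gsta2 at -2.92 and Gsta3 at -2.80. Antioxidant enzymes had 6 falls and 1 rise among 9 (median -0.36), with Sod2 at -1.18 and the metallothionein Mt1 at 1.40. Adjusted p from camera with a preset correlation lay between 1.1e-13 for myeloid genes and 0.032 for antioxidant enzymes, and no call of these 17 lists held with an estimated correlation (adjusted p from 0.096 for tubular injury to 0.24 for Nrf2 targets). The antioxidant call also ended with quantile normalization (adjusted p = 0.11). Adjusted over the list alone, 27 proximal tubule transporters, 22 myeloid and 28 oxidative phosphorylation genes passed.

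At ip 400 mg/kg 3526 of 5748 genes passed in limma, 2086 up and 1440 down, and 1348 of them changed over 2-fold. The share of rises was 59.2%, or 44.3% with median centring of each array, which moved the median of all genes from 0.11 to -0.08. Without the filter on low values 4819 of 7859 genes passed, 2214 up and 2605 down, so that falls outnumbered rises.

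Lists that camera did not call at 400 mg/kg included markers of glomerular and vascular cells. Of 13 podocyte genes 4 rose by iv (median log2 fold change 0.13) and 5 rose and 2 fell by ip (median 0), and of 15 endothelial genes 1 rose and 2 fell by iv (0.01) and 4 rose and 2 fell by ip (-0.13). The lysosome list had 6 rises and 4 falls among 17 by iv (-0.08) and 6 rises and 5 falls by ip (-0.03), and p53 targets had 6 rises and 1 fall among 14 by iv (0.19) and 10 rises and 1 fall by ip (0.58). Endoplasmic reticulum stress genes had 5 rises and 1 fall among 16 by either route (0.22 by iv and 0.13 by ip). Heat shock genes had 5 rises and 1 fall among 11 by iv (0.08) and 4 rises and 5 falls by ip (-0.28). Of 8 renin and vasoactive genes 2 rose and 3 fell by iv (-0.18) and 4 rose and 3 fell by ip (0.10), and of 6 adipose genes none passed by iv (0.10) and 1 rose by ip (0.25). By iv the Nrf2 targets had 4 rises and 6 falls among 16 (-0.19) and antioxidant enzymes 1 rise and 4 falls among 9 (-0.22), and by ip the circadian list had 3 rises and 5 falls among 15 (0.01). Median and mean had opposite signs for endothelium, lysosome and, by iv, the renin list (means -0.01, 0.12 and 0.32 by iv, and 0.01 and 0.16 for endothelium and lysosome by ip), and, by ip, for heat shock and the circadian list (means 0.51 and -0.22). For adipose genes the camera direction was down although median and mean were above 0. The fry test, which does not set a list against other genes, called 21 lists by iv and 21 by ip. By iv these included podocyte genes and p53 targets (adjusted p = 0.0091 each), endoplasmic reticulum stress (0.0018), heat shock (0.0013) and, downward, antioxidant enzymes (0.01). By ip they included podocyte genes (adjusted p = 0.0037), p53 targets (2.2e-09), the renin list (0.00073) and endoplasmic reticulum stress (0.031).

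**Figure D2:**
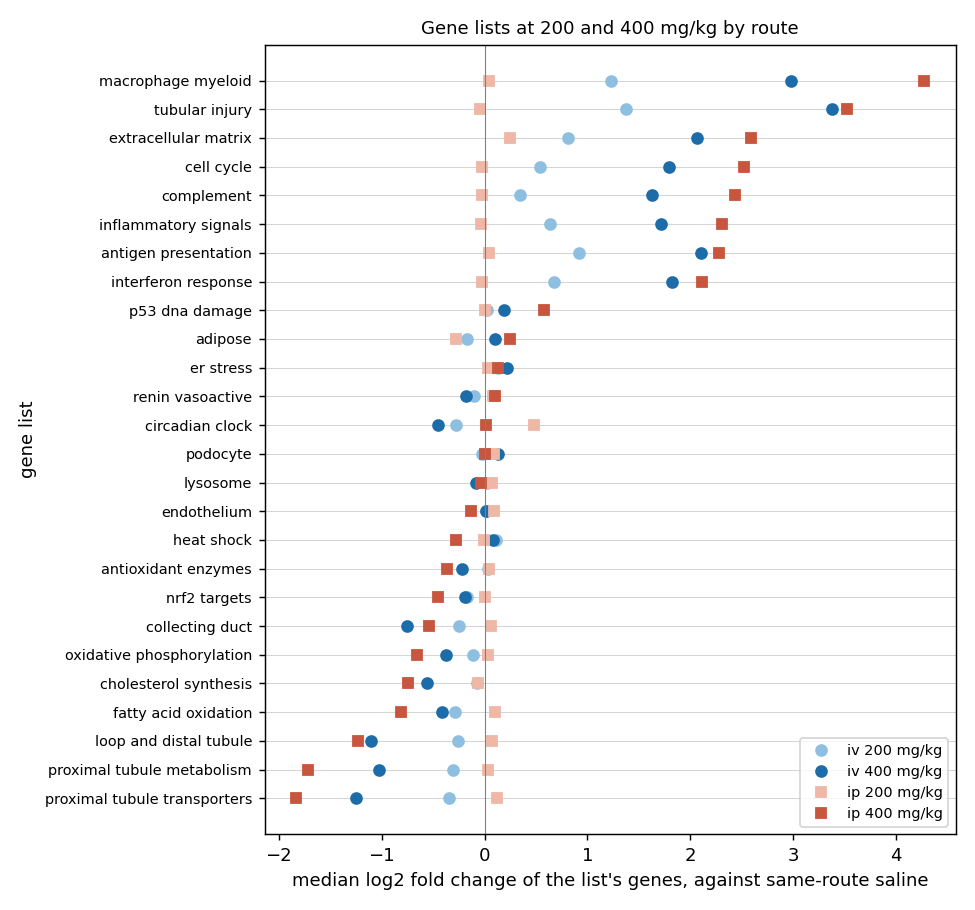
Median log2 fold change against saline of the same route (x axis) of each of 26 gene lists (y axis) at 200 and 400 mg/kg, with blue points for iv and red squares for ip. At 400 mg/kg myeloid and tubular injury genes have the highest medians by both routes and proximal tubule transporters the lowest, and the ip 200 mg/kg medians lie near 0 for most lists.

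The responses to 400 mg/kg by the 2 routes overlapped widely. Among the genes kept by the naming rule, Serpina10, Krt20, Il1f6, Lrg1, Col1a1, Socs3, Cd44 and Aoc1 were in the 10 largest rises by both routes. Hpd, Pvalb, Dnase1, Clec2h, Slc22a29, Dpys and Mep1b were in the 10 largest falls by both. Genes called up by both routes numbered 1529, where independent lists of these sizes would share 641, and genes called down by both numbered 935 against 274. Calls in opposite directions were 12, against 839 for independent lists. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.93.

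Whether the size of the 400 mg/kg effect differed by route was tested as an interaction. The immediate early genes Fos, Egr1, Nr4a1 and Csrnp1 and the Ras family gene Rasd1 differed most in the upward direction, with differences of ip minus iv effects of 5.34 ± 1.02 (SE), 4.49, 4.03, 3.05 and 3.58 (adjusted p = 0.0008 for Fos and 1.8e-07 for Rasd1). Fos fell by 2.10 by iv and rose by 3.23 by ip on the log2 scale. The differences of these 5 genes lay mostly in the saline groups. The means of Nr4a1 were 10.12 in iv and 5.95 in ip saline but 6.91 and 6.76 at 400 mg/kg. Those of Fos were 10.14 and 3.72 in saline and 8.03 and 6.96 at 400 mg/kg. The ip effect lay below the iv effect for Slc22a6 (difference -1.55 ± 0.43 SE, adjusted p = 0.03), Akr1c20 (-1.54), Gsta2 (-1.48), the retinol dehydrogenase Rdh5 (-1.36) and Nphs1 (-0.96), and Fam220a differed by -1.51. The call on Slc22a6 ended in a fit of the 4 groups alone (adjusted p = 0.16).

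In the interaction camera called 13 lists with the preset correlation and none of them with an estimated correlation (adjusted p from 0.3 to 0.54), and fry called 8. Among myeloid genes 4 of 22 had a larger rise by ip (median difference 0.96), including Ms4a7 (2.49), Ccr2 (2.12) and Itgam (1.76), and 4 of 27 proximal tubule transporters fell further by ip (median -0.70), including Slc22a12 (-1.35) and Slc17a3 (-1.05). Circadian genes differed in both directions, with Ciart at 2.83, Per3 at 1.58 and Arntl at -1.19. The size for Arntl is approximate, since its means in iv saline (3.00) and at iv 400 mg/kg (3.29) lay under 3.47. In the inflammatory list, Ptgs2, the inducible cyclooxygenase, differed by 2.45, Relb by 1.31 and Cxcl9 by 1.51. Extracellular matrix (median 0.72, Vcan 1.87) and p53 targets (median 0.20, Plk3 2.35, Plk2 1.56) were also called up. Plk3 and Plk2 were the only 2 of 14 p53 targets that passed singly, and both also stand in the immediate early list. Plk3 did not rise by ip (-0.12), and its difference came from a fall of 2.47 by iv. The lists called down were proximal tubule metabolism (median -0.56, with Ddc at -1.09 and Cyp7b1 at 1.25), oxidative phosphorylation (-0.28, Atp5d -0.49), Nrf2 targets (-0.36), antioxidant enzymes (-0.28, Txn2 -0.67), fatty acid oxidation (-0.37), loop and distal tubule (-0.28) and cholesterol synthesis (-0.32).

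The interaction test called 248 genes, 169 up and 79 down. The 95% interval of the route difference was -1.49 to 0.90 for Havcr1, -1.53 to 0.36 for Clu and -0.69 to 1.62 for Cd14, so differences of up to those sizes were not excluded. The count was between 148 (without ip mouse 104) and 530 (without ip mouse 107) when single mice were left out, with 153 without iv mouse 44, 158 without iv mouse 45, 463 without iv mouse 48 and 150 without ip mouse 108. It was 76 in a fit of the 4 groups alone and 643 with array weights. With quantile normalization 213 genes were called, 155 of them among the 248 and in the same direction. The share of rises went from 68.1% to 48.4% in that setting.

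At iv 200 mg/kg, a middle dose, the injury genes were raised to differing extents between mice. Serpina10 rose by 5.46 ± 0.61 (log2 fold change, SE, adjusted p = 1.9e-08), Lrg1 by 3.23, Col1a1 by 3.18, Clu by 3.01 and Timd2 by 2.72, each in 6 of 6 mice against the saline mean. Havcr1 rose by 2.48 to 12.12 ± 1.47 (SD, n = 6, adjusted p = 8e-05), a wider spread than the 0.59 of iv saline. The largest falls were in the immediate early genes Nr4a1 (-3.86), Fos (-3.21), Csrnp1 (-2.56) and Egr1 (-2.55) and in the mitochondrial carrier Slc25a25 (-3.19).

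At iv 200 mg/kg camera called 16 lists with the preset correlation and none with an estimated correlation (adjusted p from 0.15 to 0.37 with an estimated correlation), and fry called 9. Those that rose were tubular injury (14 of 21 genes, median 1.37, Lgals3 1.48), myeloid genes (14 of 22, 1.23, Cd14 2.55), antigen presentation (8 of 10, 0.92, H2-DMa 1.45), extracellular matrix (13 of 22, 0.81, Col1a2 2.39), interferon response (7 of 19, 0.67, Gbp2 1.30), inflammatory signals (8 of 15 with 1 fall, 0.64, Ccl5 2.01), cell cycle (8 of 22, 0.54, Rrm2 2.25) and complement (4 of 12, 0.34, Cfi 2.23). The lists called down had few genes that passed singly: 4 of 27 proximal tubule transporters fell and 1 rose (median -0.35, Slc22a12 -0.75), 2 of 15 circadian genes (-0.28, Ciart -1.48), 1 of 26 metabolism genes (-0.31, Ddc -0.60), 1 of 13 collecting duct genes (-0.25, Scnn1a -0.45), 1 of 29 oxidative phosphorylation genes (-0.11, Sdha -0.32), 1 of 16 Nrf2 targets (-0.17, Osgin1 -0.59), and none of the 19 fatty acid oxidation or the 17 loop and distal tubule genes (-0.29 and -0.26). With an estimated correlation adjusted p was 0.15 for tubular injury and 0.26 for proximal tubule transporters.

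In all, limma called 423 genes at iv 200 mg/kg, 349 up and 74 down. The count was 76 when only the 2 groups were fitted, 271 without mouse 25 and 1398 with array weights, and the share of rises was 82.5%, or 66.6% with quantile normalization and 54.5% with median centring. Of the 423 genes, 402 were called in the same direction at iv 400 mg/kg and none in the opposite, where independent lists would share 121 and 89.1. The covariance of the 2 sets of fold changes was 0.279, against 0.018 simulated for unchanged groups sharing the same saline arrays and 0.265 with the saline arrays split between the comparisons.

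**Figure D3:**
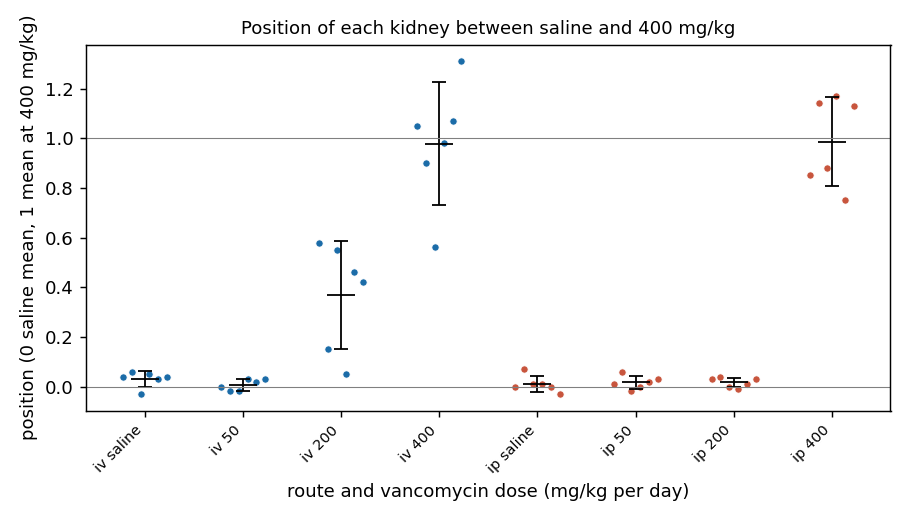
Position of each kidney (y axis, no unit) on the line from the saline mean at 0 to the 400 mg/kg mean at 1 of its route, by group (x axis), with points for mice and bars for the mean and SD of 6 mice. The iv 200 mg/kg kidneys lie between 0.05 and 0.58, and the ip 200 mg/kg kidneys near 0.

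At ip 200 mg/kg, by contrast, the genes that passed were few and belonged mainly to the circadian clock. Dbp (1.98 ± 0.29 SE, adjusted p = 6.6e-05) and Per3 (1.54 ± 0.23) rose together with Rtkn (0.49), and Arntl, which encodes the clock activator BMAL1, and its partner Npas2 fell by 1.33 and 1.20 on the log2 scale. Each of these 5 genes lay on 1 side of the saline mean in 6 of 6 mice. Havcr1 was at 0.77 above ip saline and did not pass. The circadian list was called (median 0.48, 2 rises and 2 falls among 15 genes, 10 adjusted over the list alone, adjusted p = 2e-06, or 0.054 with an estimated correlation), and so was the extracellular matrix list, in which no gene passed singly (median 0.25, adjusted p = 8.5e-05, or 0.78 with an estimated correlation). These 5 genes were all that limma called of 5748, with 143 at an unadjusted p under 0.05. Quantile normalization left 3, as did leaving out saline mouse 63 or 64 or treated mouse 85, 86 or 89. Whether the 200 mg/kg effects differed by route was tested after the counts were seen, and 18 genes passed with a higher and 38 with a lower value by ip. The same test at 50 mg/kg gave 11 genes with a higher and 0 with a lower value by ip.

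Between 200 and 400 mg/kg the iv kidneys gained further in Cd44 (3.82 ± 0.33 SE), Krt20 (3.71), Il1f6 (3.40), Ccl9 (3.32) and the chemokine gene Ccl6 (3.27), and Hpd (-5.48), Pvalb (-3.40), Dnase1 (-3.30), Hsd3b2 (-2.94) and Clec2h (-2.91) fell further. Havcr1 was 1.07 higher at 400 than at 200 mg/kg by iv (adjusted p = 0.046), a call that ended with quantile normalization (adjusted p = 0.057), and Clu was 1.14 higher. By ip, Il1f6 (7.24), Serpina10 (7.13), Cd44 (6.82), Krt20 (6.68) and Slc34a2 (6.55) rose and Hpd (-7.86), Dnase1 (-6.04), Pvalb (-6.03), Aspdh (-5.10) and Slc22a22 (-4.97) fell between the doses, and Havcr1 rose by 2.48. Among myeloid genes 21 of 22 rose between the iv doses (median 1.85, Fcgr1 3.06) and all 22 between the ip doses (4.17), and among proximal tubule transporters 19 of 27 fell between the iv doses with 1 rise (-0.86, Lrp2 -1.61) and 26 of 27 between the ip doses with 1 rise (-1.95). The camera calls between the doses, 16 lists by iv and 18 by ip, were all lost with an estimated correlation (adjusted p from 0.072 by iv and from 0.11 by ip). limma called 1796 genes between the iv doses (1026 up, 770 down) and 3481 between the ip doses (2024 up, 1457 down), and with median centring the shares of rises went from 57.1% to 46.6% and from 58.1% to 44.4%.

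The lowest dose was compared with saline of each route. At iv 50 mg/kg 29 of the 31 genes called fell, and the largest falls were in immediate early genes, of which 9 of 16 fell in a list written after some had been seen. Fos fell by 4.41 ± 0.72 (log2, SE, adjusted p = 0.00012), Nr4a1 by 4.18 ± 0.41 (adjusted p = 1.2e-09), Egr1 by 3.87, the stress kinase gene Plk3 by 2.63 and Slc25a25 by 2.59, each in 6 of 6 mice. Zfp418 rose by 0.59 (adjusted p = 0.045), a call lost with array weights (adjusted p = 0.06). At ip 50 mg/kg the clock genes Ciart (1.86 ± 0.37), Dbp (1.68) and Per3 (1.21) rose, and Npas2 and Arntl fell by 1.18 and 1.04. None of the tested tubular injury genes passed at 50 mg/kg by iv or at 50 or 200 mg/kg by ip.

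Of the lists at iv 50 mg/kg, p53 targets were called down (median -0.08, adjusted p = 0.0047, or 0.13 with an estimated correlation). Of its 14 genes Plk3 passed, and 2 genes passed adjusted over the list alone, with Cdkn1a at -1.17 (adjusted p = 0.08 over all genes). At ip 50 mg/kg the circadian list was called up (median 0.43, 3 rises and 2 falls among 15 genes, adjusted p = 9.1e-07) and kept its call with an estimated correlation (adjusted p = 0.042). Interferon response (median -0.08) and adipose genes (-0.43) were called down with no gene passing singly, and both calls were lost with an estimated correlation (adjusted p = 0.94 and 0.58). In limma 31 genes passed at iv 50 mg/kg (2 up, 29 down) and 5 at ip 50 mg/kg (3 up, 2 down), with 245 and 108 at an unadjusted p under 0.05. The ip count was 0 when only the 2 groups were fitted and 13 with array weights, 1 without treated mouse 72, 2 without saline mouse 61, 63 or 64 or treated mouse 69 or 71, and 3 without treated mouse 67 or 70. The iv count was 90 with array weights. Of the 31 iv genes 16 were called in the same direction at iv 400 mg/kg and 3 in the opposite, with 6.12 and 9.29 for independent lists. The covariance of these fold changes was 0.0112, against 0.018 simulated for unchanged groups sharing the saline arrays and -0.00314 with the saline arrays split, so the overlap is not read as a shared effect.

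The saline groups of the routes were compared to find what route alone or array handling set apart. Of 16 immediate early genes in the list written after some had been seen, 11 were lower in ip saline than in iv saline kidneys and 2 higher (median -1.43, or -0.91 with sets of arrays that vary together as a block), and of the 9 not seen before 4 were lower and 2 higher (median -0.31). Fos fell by 6.41 ± 0.72 (log2, SE, from 10.14 ± 0.56 to 3.72 ± 0.73, SD, n = 6 per group, adjusted p = 7e-10), Nr4a1 by 4.18, Egr1 by 3.98, Plk3 by 3.77 and Rasd1 by 3.56, while Mcl1 (0.58) and Ier5 (0.61) rose. Clock genes differed too, with Ciart at -3.37, Arntl at 2.00 and Clock at 1.39. The iv saline mean of Arntl (3.00) lay under 3.47, so the size of its difference is approximate. The largest rises were in Ip6k2 (2.28), the importin gene Kpna4 (2.26), Dmxl1 (2.21), Tmem123 (2.09) and Retreg3 (2.00). Umod (0.85), Nphs1 (0.82) and Lrp2 (0.63) were also higher by ip, but with quantile normalization Nphs1 and Lrp2 no longer passed (adjusted p = 0.18 and 0.16).

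**Figure D4:**
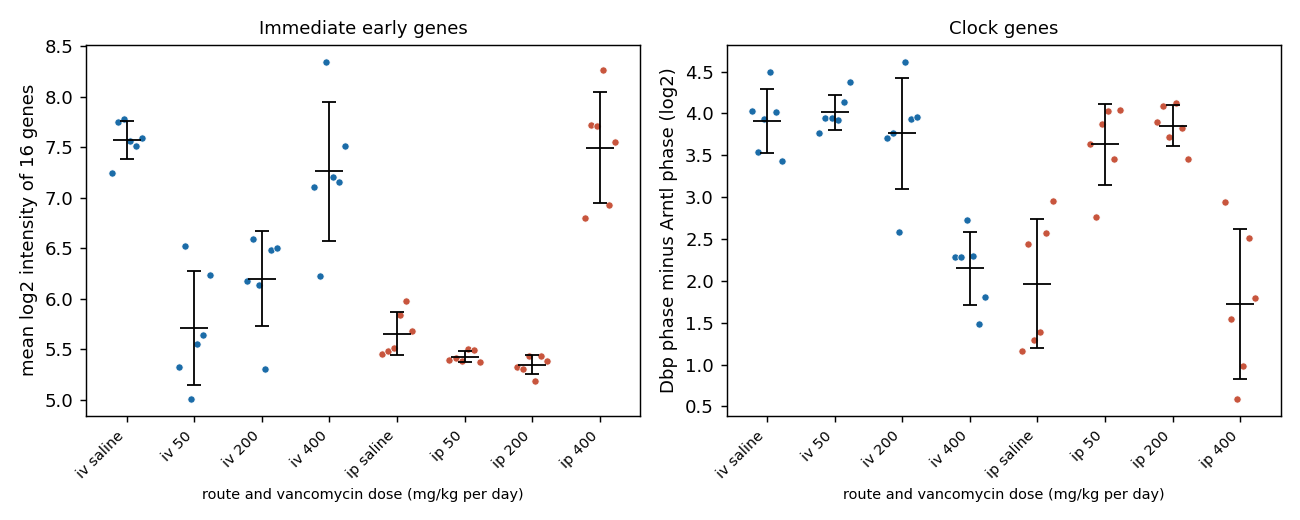
Mean log2 intensity of 16 immediate early genes (left) and the log2 level of clock genes of the Dbp phase minus those of the Arntl phase (right) in each kidney by route and dose (x axis), with points for mice and bars for the mean and SD of 6 mice. The immediate early mean is 7.57 ± 0.19 in iv saline and 5.66 ± 0.22 in ip saline. The clock difference is 1.97 ± 0.77 in ip saline against 3.63 ± 0.48 at ip 50, 3.85 ± 0.25 at ip 200 and 1.73 ± 0.89 at ip 400 mg/kg. By iv the clock difference is 3.91 ± 0.38 in saline against 2.15 ± 0.43 at 400 mg/kg. Arntl and Npas2 lay under 3.47 in all iv groups, so the iv clock differences are approximate.

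Of 5748 genes, 3168 were higher and 148 lower in ip saline, and the median over all genes was 0.41. With quantile normalization 1344 genes passed, 626 up and 718 down, 770 of them called in the same direction as before, and the median was -0.04; with median centring 1597 passed, 598 up and 999 down. Effects of vancomycin by the 2 routes are therefore compared relative to saline of the same route. Direct differences in level between the routes carry this limit. Subtracting saline of the same route removes a shift but not a difference in the spread of values. The 90th percentile lay between 8.28 and 8.75 in iv arrays and between 9.07 and 9.23 in ip arrays. Route differences in effect thus carry a limit too, and 155 of the 248 interaction calls held with quantile normalization. Which arrays were normalized together is not given in the sources used here. Relative to the other genes, 6 lists were called down: tubular injury (median 0.04, with 3 rises such as Tmsb10 at 0.76 and 2 falls such as Ankrd1 at -0.95), inflammatory signals (median 0, with Ptgs2 at -1.60 and Tlr4 at 1.15), extracellular matrix (0.12, with 3 rises such as Col18a1 at 0.70), cell cycle (0.09, with 4 rises such as Mcm2 at 0.73), myeloid genes (0.13, with 4 rises such as Fcgr2b at 0.64 and 1 fall) and the circadian list (-0.18). No such call was left with quantile normalization or with an estimated correlation (adjusted p from 0.45 to 0.95). Apart from the circadian list their medians were not below 0, since camera set them against a median of 0.41. The fry test called none of these 6 lists (adjusted p from 0.45 to 0.91) and called 16 others, all up.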

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

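The tests of the immediate early genes and of the clock genes below, and the lists they use, were chosen after the results were seen. The splits of the samples were not. The prediction on the spread at iv 200 mg/kg was written beforehand, but the sets of arrays it uses were found from the values.

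Immediate early genes, which respond to stimuli within minutes, were higher in iv saline kidneys than in the iv 50 and 200 mg/kg groups and in ip saline. Over 16 such genes the median change was -2.02 at iv 50 mg/kg, -1.10 at iv 200 mg/kg and -1.43 in ip saline against iv saline (-0.91 with sets of arrays that vary together as a block and -1.92 with quantile normalization), but over the 9 members not seen before it was -0.71, -0.25 and -0.31, so the pattern rests mostly on genes already seen. At iv 400 mg/kg the median was -0.16, with 6 rises and 7 falls, and over the unseen members it was 0.98, with 6 rises and 0 falls by limma. For a lowering by vancomycin through either route, the medians were -0.12 at ip 50, -0.23 at ip 200 and 2.10 at ip 400 mg/kg. The mean of these genes in ip saline (5.66) already lay near that at iv 50 mg/kg (5.72). A lowering thus had little room to show at ip 50 and 200 mg/kg, and only the rise at ip 400 mg/kg goes against it, for that dose. The low-spread arrays of iv saline mouse 1 and iv 50 mg/kg mouse 9, as the whole cause, are argued against by a median of -1.89 at iv 50 mg/kg without these and ip 200 mg/kg mouse 88. Handling or order of sampling of the iv saline mice may differ, which the labels do not give. An effect of vancomycin by the iv route stays open. The rise of the unseen members at iv 400 mg/kg does not decide it for the lower doses, since all 9 also rose at ip 400 mg/kg (median 2.22).

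Genes of the Dbp phase minus those of the Arntl phase stood at 1.97 in ip saline, 3.63 at ip 50 and 3.85 at ip 200 mg/kg (group mean log2). The difference stood at 1.73 at ip 400 mg/kg, 3.91 in iv saline and 2.15 at iv 400 mg/kg, so low values were not confined to ip saline. The low value at iv 400 mg/kg came mainly from the Dbp phase. Against iv saline 7 of its 9 genes fell (median -1.25), and 0 of 4 Arntl phase genes passed (median 0.31). At ip 200 mg/kg against ip saline the 2 phases moved in opposite directions (medians 0.71 and -1.1). Arntl and Npas2 lay under 3.47 in all iv groups, so the iv values are approximate. The 6 members of the Dbp phase not seen before had a median change of 0.51 at ip 200 mg/kg and the 2 of the Arntl phase -0.68, a difference of 1.19 (0.97 at ip 50 mg/kg), which goes with a shift of the ip saline mice in clock phase as a candidate explanation. With sets of arrays that vary together as a block the difference over all members was 1.69 (1.81 without), which decides nothing, since the sets were found within groups and no set differs by more than 1 array between ip saline and ip 200 mg/kg. Time of day at sampling is not given by the labels, and an effect of vancomycin on the clock stays open and untested.

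The iv 200 mg/kg kidneys differed widely in their position between iv saline (0) and iv 400 mg/kg (1), with 0.58, 0.15, 0.55, 0.05, 0.46 and 0.42 for mice 25 to 30. The iv 400 mg/kg kidneys spread about as widely, from 0.56 to 1.31 (SD 0.25, against 0.22 at iv 200 mg/kg). The SD was 0.18 at ip 400 mg/kg. A wide spread was thus not particular to iv 200 mg/kg. With the sets of arrays taken out, the range of the iv 200 mg/kg kidneys was still 5.27 times that of iv saline (0.60 against 0.11). The sets were found with the line from saline to 400 mg/kg removed, so they could hardly account for spread along it. This test therefore decides little, although mice 27 to 30 fell in the same set and still ranged from 0.05 to 0.55. A difference between mice in response may remain, as a hypothesis, and differences in the dose received were not tested.

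Of 100 splits of the same arrays, the number that called as many genes as the real groups was counted, the real split included. It was 1 for iv 200 (real 423, highest other 414), iv 400 (2368), ip 50 (2), ip 200 (0) and ip 400 mg/kg (2731). The number was also 1 for ip against iv saline (2276), the interaction (real 248, highest other 210) and ip 400 against 200 mg/kg (2780). No other split called as many genes in these comparisons, a share under 5%, though the margin was small for iv 200 mg/kg and the interaction. A number of 1 is the lowest that 100 splits can give, and the shares were not adjusted over the 10 comparisons. The ip 50 mg/kg count of 5 was 0 when only the 2 groups were fitted. For iv 400 against 200 mg/kg the number of splits was 2, since another split called 1913 genes, above the real 1796. That share also lies under 5%, although the real count was not the highest. For iv 50 mg/kg 9 of 100 splits called as many as the real 31, a share above 5%, so the splits do not tell this count from chance. The highest other split there, 1206 genes, points to a structure of the samples, so these splits may not measure chance alone. Splits without the low-spread arrays of iv saline mouse 1 and iv 50 mg/kg mouse 9 were not run.

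Among 364 groups of 6 values tested, 30 held a mouse far from the other 5, where chance gives about 5%. The 90th percentile of log2 values was 8.29 in iv saline mouse 1 (others 8.68 to 8.75), 8.28 in iv 50 mg/kg mouse 9 (8.62 to 8.72) and 9.07 in ip 200 mg/kg mouse 88 (9.15 to 9.2). The same iv saline mouse 1 stood apart in Clu (9.05, others 10.05 to 10.49), Cfb (9.51, others from 10.26), Il1f6 (3.98, others up to 2.3), Aoc1 (3.53, others from 5.38), Acox2 (9.8, others from 10.48), Ppargc1a (9.54, others up to 9.23) and Ndufs1 (11.14, others from 11.73). In the other iv saline mice, mouse 2 stood apart in Nphs1 (4.73, others from 5.32), mouse 3 in Clec2h (7.43, others from 7.93) and in position (-0.03, others from 0.03), mouse 5 in Aurka (2.29, others up to 2.13) and mouse 6 in Cxcl10 (5.23, others up to 4.74). At iv 400 mg/kg, mouse 45 stood apart toward the saline level in Cd14 (9.74, others from 11.13), Clec2h (6.32, others up to 3.99), Dpys (4.18, others up to 3.08) and Slc7a8 (7.53, others up to 6.53), and its position was 0.56.

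In ip saline, mouse 61 stood apart in Clec2h (10.33, others up to 9.53), mouse 62 in Slc7a8 (8.44, others from 9.3) and mouse 63 in Serpina10 (5.27, others up to 3.51) and Sdha (12.03, others from 12.23). At ip 50 mg/kg it was mouse 67 in Cdkn1a (7.08, others up to 6.15) and mouse 71 in Slc34a1 (13.13, others from 13.39). At ip 400 mg/kg it was mouse 105 in Aoc1 (10.17, others from 11.29) and H2-DMa (6.48, others from 7.5), mouse 106 in Ankrd1 (9.85, others up to 8.13) and Slc22a12 (7.95, others from 9.24), and mouse 107 in Serpina10 (11.38, others from 11.65).

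The interaction test found the 400 mg/kg effect to differ by route (ip minus iv, log2) in 29 of the named genes. The difference was 5.34 for Fos, 4.49 for Egr1, 4.03 for Nr4a1, 3.58 for Rasd1, 3.05 for Csrnp1, 2.83 for Ciart, 2.49 for Ms4a7, 2.45 for Ptgs2, 2.35 for Plk3, 2.12 for Ccr2, 1.87 for Vcan, 1.76 for Itgam, 1.58 for Per3, 1.56 for Plk2, 1.51 for Cxcl9, 1.31 for Relb and 1.25 for Cyp7b1. It was -1.55 for Slc22a6, -1.54 for Akr1c20, -1.51 for Fam220a, -1.48 for Gsta2, -1.36 for Rdh5, -1.35 for Slc22a12, -1.19 for Arntl, -1.09 for Ddc, -1.05 for Slc17a3, -0.96 for Nphs1, -0.67 for Txn2 and -0.49 for Atp5d. Fos, Egr1, Nr4a1, Rasd1, Csrnp1, Plk3, Ciart, Per3, Arntl, Ptgs2, Relb, Ddc, Nphs1, Rdh5, Fam220a and Akr1c20 also passed the test between the saline groups, so that their differences may rest on the saline levels. For Nr4a1, Rasd1 and Csrnp1 the means at 400 mg/kg were close by iv and ip (6.91 and 6.76, 6.53 and 6.55, 5.85 and 6.04). In saline they were 10.12 and 5.95, 7.64 and 4.08, and 7.65 and 4.79.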

How the results depend on the processing

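Names as listed, the block, the arrays with a low 90th percentile and the interactions at lower doses were chosen after the data were seen. Across the settings run, single mice left out apart, 1924 values of named genes kept direction and side of the threshold, 72 lost and 50 gained the call, and 2 reversed. Of the counts of genes 100 stayed within 1.5 times and 40 did not, and of the counts of lists 29 and 31. Counts at iv 400 and ip 400 mg/kg moved beyond 1.5 times only when other probe sets or names entered. The list calls rest on the preset correlation and on the reconstructed names. In simulation 32% of log2 changes of 0.5 were recovered for iv 400 mg/kg and 11% for the interaction, so a gene that was not called may still have changed. The RNA quality covariate was not run, and no paired analysis was run, since no mouse number is shared between groups. The sets of arrays with shared residuals largely followed mouse order, and mice 61, 62, 67, 68, 85, 86, 103 and 104 made up an ip set. The main fit has no block for these sets. With the block 3343 genes were called at iv 400 mg/kg and 764 in the interaction, against 2859 and 248 without. Unless a value or the setting itself shows it, the cause was not tested.

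With a filter at the 75th percentile 3 genes were called at ip 50, 3 at ip 200 mg/kg and 63 in the interaction. With all 24930 probe sets that passed the filter, which need no names, more features were tested and the calls were 196 at iv 50, 1342 at iv 200, 10279 at iv 400, 4 at ip 50, 5 at ip 200, 14250 at ip 400, 6028 and 13770 for 400 against 200 mg/kg by iv and ip, 14430 between the saline groups, 1331 in the interaction and 8596 shared by the routes. Names as listed gave 110, 872 and 5835 genes at iv 50, 200 and 400, 2, 3 and 7624 at ip 50, 200 and 400, 3471 and 7439 for 400 against 200 mg/kg by iv and ip, 7820 between the saline groups and 644 in the interaction.

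Quantile normalization gave 3 genes at ip 50, 3 at ip 200 mg/kg and 1344 between the saline groups, and median centring 1597 there. Array weights gave 90 at iv 50, 1398 at iv 200, 13 at ip 50, 18 at ip 200 mg/kg and 643 in the interaction. Fitting only the groups compared gave 76 at iv 200, 0 at ip 50 mg/kg (limma, 261 at an unadjusted p under 0.05) and 76 in the interaction. An adjusted p under 0.01 left 211 at iv 200, 2 at ip 50, 3 at ip 200 mg/kg and 91 in the interaction. Without the arrays of low 90th percentile 3 were called at ip 200 mg/kg, and with the block 3 at ip 50 mg/kg and 764 in the interaction. Ccnd1 between the saline groups went from 0.40 to -0.04 with quantile normalization, and Laptm5 from 0.36 to -0.18 with the mean of its probe sets.

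With an estimated correlation camera called 0 lists in every comparison except ip 50 mg/kg (1), with 1 to 11 at an unadjusted p under 0.05, and with names as listed 0 in every comparison, with 0 to 3. fry called 0 at iv 50 (unadjusted 2), 9 at iv 200 (8 up), 0 at ip 50 (unadjusted 1), 0 at ip 200 mg/kg (unadjusted 1), 16 between the saline groups (all up, where camera's 6 were all down) and 8 in the interaction (4 up, 4 down). At iv 50 mg/kg 2 lists were called with quantile normalization and 2 without the arrays of low 90th percentile. Without a filter 6 were called at ip 200 mg/kg and 1 between the saline groups, where quantile normalization left 0 (unadjusted 2). With 3 saline arrays for 400 mg/kg and the other 3 for the lower dose, the genes called at both numbered 224 at iv 200, 9.5 at iv 50, 1.5 at ip 200 and 0.5 at ip 50 mg/kg (means over both assignments).

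Leaving out each mouse gave 25 to 34 genes at iv 50, 271 to 590 at iv 200, 2567 to 2937 at iv 400, 1 to 6 at ip 50, 3 to 7 at ip 200, 3293 to 3530 at ip 400 mg/kg, 1438 to 1971 and 3289 to 3493 for 400 against 200 mg/kg by iv and ip, 2844 to 3367 between the saline groups and 148 to 530 in the interaction. The mice that moved a count beyond 1.5 times were iv 200 mg/kg mouse 25 (271), for the interaction iv 400 mg/kg mice 44 (153), 45 (158) and 48 (463) and ip 400 mg/kg mice 104 (148), 107 (530) and 108 (150), at ip 50 mg/kg mice 61, 63, 64, 69 and 71 (2 each), 67 and 70 (3 each) and 72 (1), and at ip 200 mg/kg mice 63, 64, 85, 86 and 89 (3 each). The share of rises went from 82.5% to 67.6% at iv 200 mg/kg without the arrays of low 90th percentile, and between the saline groups from 95.5% to 46.6% with quantile normalization and 37.4% with centring.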

Other observations

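The members named here, and the list of immediate early genes, were chosen after their values were seen. Among genes of lists that were not called, single members still moved far at 400 mg/kg. Hspb1, a small heat shock protein, rose by 3.32 by iv and 3.47 by ip on the log2 scale, and Hspb8 by 1.78 and 2.95. Asns, asparagine synthetase, rose by 2.67 and 3.19. In the vasoactive list, angiotensinogen, Agt, rose by 3.39 and 4.25 and the prostaglandin receptor Ptger4 by 2.07 and 2.72, while the angiotensin-converting enzyme Ace fell by 0.96 and 1.70 and the vasopressin receptor Avpr1a by 1.37 and 1.77.

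Immediate early genes were again high at ip 400 mg/kg, where 13 of 16 rose and 1 fell against ip saline (median 2.10), and all 9 members not seen before rose (median 2.22). Myc went from 3.97 in ip saline to 7.69 and from 3.89 in iv saline to 6.96 at 400 mg/kg (group mean log2 intensity), and Klf6 from 3.49 to 7.09 by ip and from 4.52 to 6.27 by iv.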
